A study of Mus musculus with 12 samples.

How the data were processed

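Total RNA from the femoral arteries of 12 male mice was measured on Affymetrix arrays after labelling as biotinylated cRNA, with 1 array per animal and 3 animals in each of 4 groups. The deposited table held log2 intensities of 23748 probe sets in 12 columns. The submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes and summarises probes). Its version, its software and the array model were not given in the sources used here. Sorted values were identical in 11 arrays and differed by at most 0.00187 in the other, so the deposited log2 values were already quantile normalized across arrays. No further normalization was applied before testing. The number of arrays limits the precision of every value.

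Probe sets carried Entrez gene numbers, 1 probe set per gene, and were named from the supplied gene tables (RefSeq annotation of the assembly GRCm38.p6, used for names, gene types and neighbour order and for no coordinates). Of the 23748 probe sets, 23111 had 1 symbol, 0 had several and 637 had none. The unnamed probe sets were left out of the tests and are not named here. Genes whose mean over the 12 arrays lay under the 25th percentile of all probe sets (4.57 log2) were left out as too dim, which removed 5830 genes and left 17281.

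Differences were tested with limma 3.58.1 in R 4.3.3, and tables and plots were made with Python 3.11.15. A model of the 4 group means was fitted to each gene, with the spread pooled over groups (8 residual degrees of freedom) and moderated across genes (2.31 prior degrees of freedom). The 7 contrasts were DOCA/salt against untreated in WT and in knockouts, knockout against WT in untreated and in treated animals, the difference between the genotypes' responses (interaction), and the averages of treatment over genotypes and of genotype over treatments. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each contrast. A gene passed at an adjusted p under 0.05, and all adjusted p-values of genes in the text are from limma.

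Of 45 gene lists, 27 described functions or genome regions and 18 were markers of cell types that an excised artery could hold or carry along. The 44 lists with at least 5 tested members were tested in limma with camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01. P-values of lists were adjusted over the 44 lists of a contrast. Results are given for part of the lists, and those of the others are not reported here. Each list was also tested with camera at an estimated correlation and with fry, whose p-value tests whether a list's genes move, on balance, in 1 direction and does not compare them with other genes. The samples, contrasts, lists, rule for naming genes and first set of alternative settings were fixed before the data were examined.

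Genes were named by rule. Rgs5 was named in every array. For each of the 5 contrasts other than the averages, up to 10 genes per direction were taken with the largest change among those that passed and whose arrays did not overlap between the groups compared, and 5 per direction for the averages. For 3 arrays against 3, chance gives no overlap in 10% of genes. The interaction required only that a gene passed. Predicted models, microRNAs and small nucleolar RNAs were counted but passed over in this naming. From a list, the 4 members with the smallest p-values and any member that passed over all genes could be named. Genes named for other reasons are said to have been chosen after their values were seen.

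The alternative settings fixed at that point were no filter on dim genes and one at the median, quantile normalization again, subtraction of array medians, trended and robust variance, the mean of a gene's probe sets, every probe set on its own, a fit to only the groups compared, array weights, the replicate number as a block, a minimum change of 1.5-fold, a test against a change of 1.2-fold, the other set tests and leaving out each array in turn. Alternatives chosen after seeing the data left out small noncoding RNAs, used the adipocyte marker level as a covariate, or left out both arrays that stood apart. Replicate numbers did not pair the arrays: the 18 pairs with the same number had residual correlations from -0.243 to 0.271 with a mean of -0.021, so the block appears only among the alternatives. On simulated data of 17281 genes with 100 genes changed at each size, the DOCA/salt contrast in WT recovered 94% of 2-fold and 87% of 1.5-fold changes, with 3.2% of 187 calls false. The interaction recovered 87% of 2-fold and 70% of 1.5-fold changes, with 5.4% of 166 calls false. The simulated noise was normal and independent between genes, with no array standing apart and no shift shared by a group. The real arrays had such features, so these shares do not tell how many real changes were missed. Raw scans were not analysed here.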

Results

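Gene expression was measured in femoral arteries of male mice at least 12 weeks old, with 1 array per animal and 2 arteries per animal. The animals were wild type (WT) or lacked RGS5 (regulator of G protein signalling 5), a protein abundant in arterial smooth muscle and pericytes that speeds GTP hydrolysis by Gq and Gi proteins. In each genotype 3 animals were untreated and 3 were treated for 10 days with a pellet of deoxycorticosterone acetate (DOCA, a mineralocorticoid, 50 mg/kg) and with 1% NaCl, a combination used to raise blood pressure in rodents. The arteries were described as stripped of endothelium before RNA was extracted, and the completeness of that removal was not tested. Values below are log2 intensities, differences are log2 fold changes, and errors of group means are SD with n = 3 arrays per group.

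Rgs5 was the gene with the largest genotype difference. Its level was 12.48 ± 0.14 (SD, n = 3) in untreated WT, 12.67 ± 0.09 in treated WT, 5.12 ± 0.28 in untreated knockouts and 5.31 ± 0.22 in treated knockouts. The difference was -7.36 in untreated (adjusted p = 1.61e-09) and -7.36 in treated animals (adjusted p = 1.62e-09). The knockout readings lay near the table's median of 4.95, so background limits this difference, and the position of the Rgs5 probes relative to the replaced sequence was not given in the sources used here. With DOCA/salt in WT its log2 difference was 0.19 (adjusted p = 0.793). Readings under that median limit other differences given below in the same way. These were Ifi202b and Cpa6 in WT, where both also lay under the dim limit of 4.57, Tnc and Fcer1a in knockouts, and Fcer1a, Top2a and Ccnb2 in untreated WT. Kif11 lay under the median in all 4 groups.

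**Figure D1:**
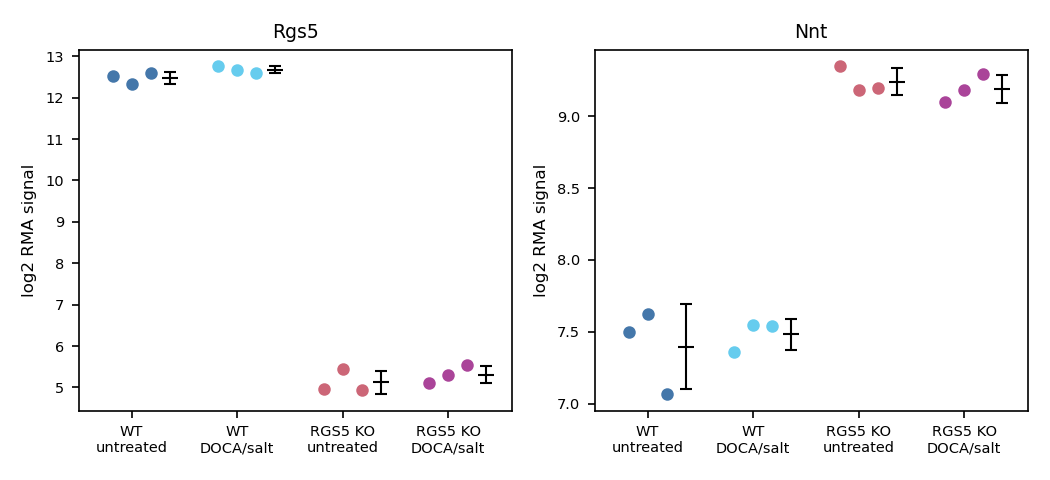
Rgs5 and Nnt expression (log2 intensity, vertical axis) in the 4 groups, with points for arrays and bars for the mean ± SD of 3 arrays. Rgs5 is near 12.5 in WT and near 5.2 in knockout arrays, and Nnt is near 7.4 in WT and near 9.2 in knockout arrays.

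Arrays that stood apart are given here because several gene groups moved with them. Array 3 of the treated knockouts had a mean of 7.41 log2 over 96 immunoglobulin segments, against 4.95 to 5.07 in the other 11 arrays, and its macrophage markers lay 0.92 log2 above their mean over all arrays. WT untreated array 1 had adipocyte markers at -0.758 log2 relative to their mean over all arrays, against 0.680 and 0.539 in the other 2 arrays of that group. Small nucleolar RNAs (snoRNAs, which guide modification of ribosomal RNA) averaged 0.392 to 0.787 log2 above their mean in the 3 WT untreated arrays and between -0.325 and -0.105 in the 9 other arrays.

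The first comparison asked how WT arteries responded to DOCA/salt. The largest increase was in Cilp, an extracellular matrix protein of cartilage and fibrotic tissue, from 6.13 ± 0.22 (SD, n = 3) to 8.0 ± 0.27, or 3.64-fold (log2 fold change 1.86, SE 0.16, adjusted p = 8.72e-04). The monocyte-attracting chemokine Ccl8 rose from 6.13 ± 0.18 to 7.90 ± 0.23 (1.77, adjusted p = 0.00513). Ptprz1 (1.38), the calcium-binding protein S100a4 (1.26), the secreted factor Ndnf (1.19), Wfdc17 (1.18), the vasodilator peptide precursor Adm (1.07), the cytokinesis protein Anln (1.07), and the TNF receptor family members Tnfrsf11b (1.04) and Tnfrsf12a (1.00) rose as well, with adjusted p from 0.00474 to 0.0468. Among the genes that fell, the matrix proteoglycan Omd fell by 1.02 (adjusted p = 0.014), Crispld2 by 0.86 (adjusted p = 0.0418) and Notch3, a receptor of mature arterial smooth muscle, by 0.76 (adjusted p = 0.0396). Also lower were Lgi1 (-0.82), the phospholipase Plce1 (-0.78), Itih4 (-0.76), Nrip2 (-0.75), the sodium pump subunit Atp1b2 (-0.74), Fam135a (-0.69) and the purinergic receptor P2ry1 (-0.68).

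Of 27 tested cell cycle genes 26 had positive values and the replication helicase subunit Mcm6 rose (0.77, adjusted p = 0.0213). Of these, 15 passed adjusted over the list alone, with values for Top2a of 0.59 and Ccnb2 of 0.41 that did not pass over all genes (camera adjusted p = 7.08e-15, and adjusted p = 0.4 with an estimated correlation). In the list of 29 extracellular matrix genes, tenascin C (Tnc) rose (0.88, adjusted p = 0.0205) and 28 did not pass over all genes. Adjusted over the list alone 9 were higher, with Timp1 at 0.66 and Loxl1 at 0.41 (camera adjusted p = 1.03e-05, and adjusted p = 0.488 with an estimated correlation). The matrix list lay at 0.192, 0.047 and -0.16 in untreated and at 0.362, 0.148 and 0.244 in treated WT arrays. Untreated array 1 thus lay above treated array 2. Synthetic smooth muscle genes, which mark cells that have left the contractile state, had 3 of 17 higher over all genes (Tnc, S100a4 and the growth factor Ccn2 at 0.84). The list had 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 4.89e-04, and adjusted p = 0.4 with an estimated correlation). Cholesterol synthesis genes were positive in 16 of 16, with Srebf2 at 0.48 and Msmo1 at 0.85. Over all genes 0 passed, and 6 did adjusted over the list alone (camera adjusted p = 1.01e-06, and adjusted p = 0.416 with an estimated correlation).

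Of 19 contractile genes Cnn1 (0.25, adjusted p = 0.0166) and Actg2 (0.42, adjusted p = 0.0356) rose and 17 did not pass over all genes. There were 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.233). Of the 23 genes of heterotrimeric G proteins and the RGS family, Gnao1 fell by 0.29 (adjusted p = 0.0384) and 3 were lower adjusted over the list alone (camera adjusted p = 0.762). Notch pathway genes shifted downward, with Notch3 lower over all genes and Hey2 at -0.38. Of the 15, 3 were lower adjusted over the list alone (camera adjusted p = 0.00114, and adjusted p = 0.416 with an estimated correlation). Among marker lists, mast cell markers shifted upward, with the IgE receptor chain Fcer1a higher (0.49, adjusted p = 0.00474). In this list 5 of 10 were higher adjusted over the list alone (camera adjusted p = 3.51e-06, and adjusted p = 0.4 with an estimated correlation). Macrophage markers had 15 of 17 positive values and 0 past the test, over all genes or adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.847 with an estimated correlation).

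By limma 155 genes passed in WT, 71 higher and 84 lower, and 54 of the lower ones were small noncoding RNAs, whose levels stood apart in the WT untreated arrays. Of the 44 lists 11 passed camera (10 upward), 0 of them with an estimated correlation and 0 by fry. The count was 70 without WT untreated array 3 and 70, 47 and 69 without WT DOCA/salt arrays 1, 2 and 3. Of the 20 named genes 4 (Cilp, Ccl8, Ndnf and Anln) passed whichever array was left out. With small RNAs left out of the fit, an alternative chosen after seeing the data, 55 genes passed.

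**Figure D2:**
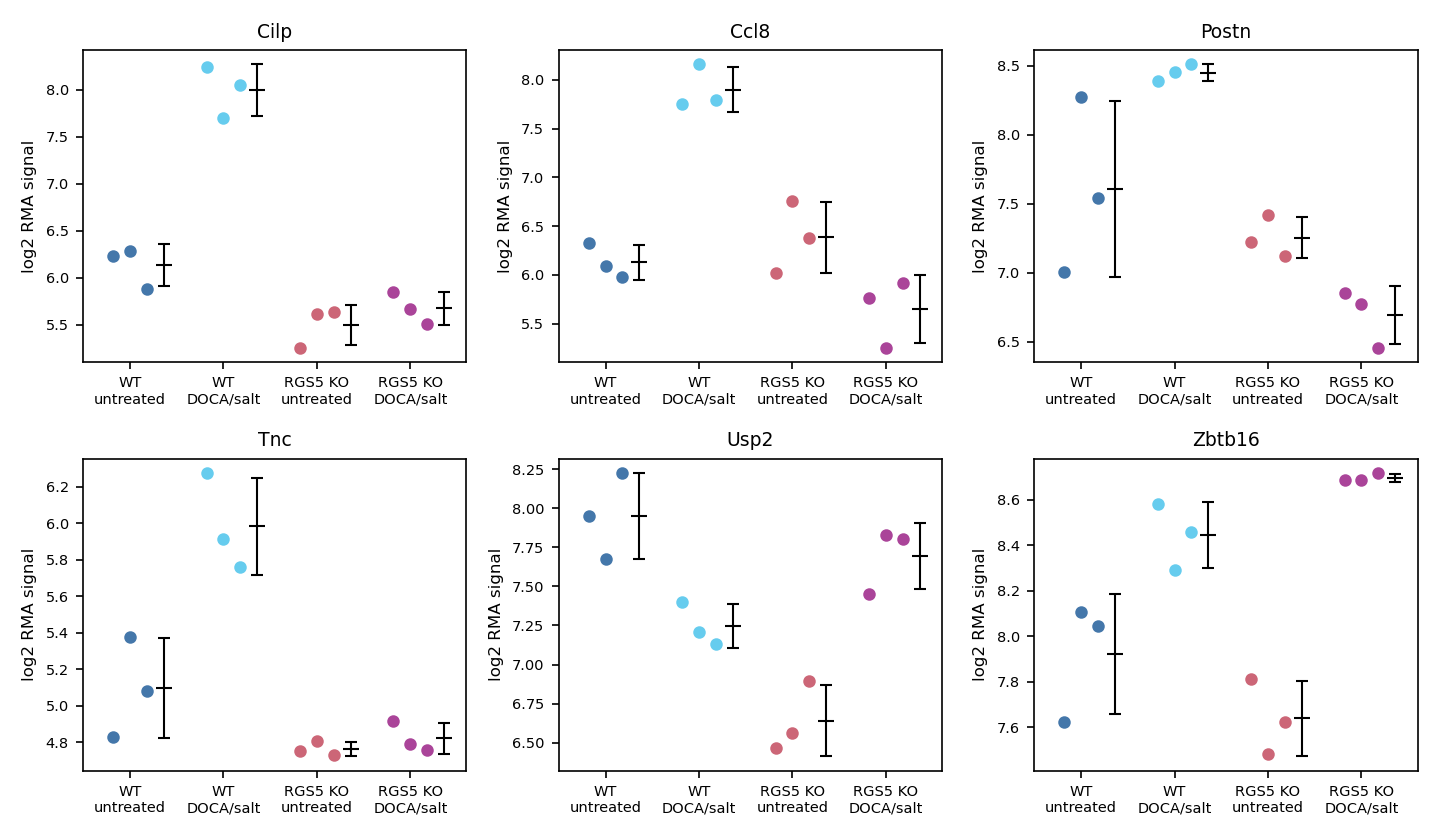
Expression (log2 intensity, vertical axes) of Cilp, Ccl8, Postn, Tnc, Usp2 and Zbtb16 in the 4 groups, with points for arrays and bars for the mean ± SD of 3 arrays. Cilp is near 8.0 in treated WT arrays and between 5.5 and 6.13 as a mean in the other groups.

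The same treatment was then examined in knockouts, where 5 genes passed and all were higher. Adm rose from 5.39 ± 0.28 (SD, n = 3) to 6.91 ± 0.32 (log2 fold change 1.52, SE 0.16, adjusted p = 0.016). The corticosteroid-induced transcription factor Zbtb16 rose from 7.64 ± 0.17 to 8.70 ± 0.02 (1.06, adjusted p = 0.0291). The proteoglycan Spock2 rose by 0.71 (adjusted p = 0.00918), the flavin monooxygenase Fmo2 by 0.67 (adjusted p = 0.0197) and the organic cation transporter Slc22a2 by 0.34 (adjusted p = 0.0462).

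Targets of the mineralocorticoid and glucocorticoid receptors moved upward in treated knockouts (camera adjusted p = 1.34e-07, adjusted p = 0.042 with an estimated correlation, fry adjusted p = 0.00796). Zbtb16 was higher over all genes and 7 of 22 were higher adjusted over the list alone. Positive values were seen in 18, and Sult1a1 (0.84), Mt2 (0.70) and Tsc22d3 (0.58) did not pass over all genes. This was the list call of the whole series that held with an estimated correlation. Adipocyte markers lay at -0.569, 0.044 and -0.593 log2 relative to their mean in the untreated and at 0.606, -0.291 and -0.174 in the treated knockout arrays. In WT the same list had 0 of 22 past the test over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.114). The interaction of this list shifted upward by camera (adjusted p = 0.00414, and adjusted p = 0.392 with an estimated correlation). The list lay at 0.102, 0.048 and 0.221 in treated WT and at 0.201, 0.073 and 0.109 in treated knockout arrays. In untreated arrays it lay at -0.139, 0.083 and 0.013 in WT and at -0.302, -0.214 and -0.197 in knockouts. The treated groups overlapped, so the difference in response came from lower untreated knockout arrays. Cholesterol synthesis genes were positive in 16 of 16 here too, with Fdft1 at 0.64 and Cyp51 at 0.85. None passed over all genes and 2 did adjusted over the list alone (camera adjusted p = 1.43e-08, and adjusted p = 0.396 with an estimated correlation). Heat shock genes were positive in 16 of 17, with 0 past the test over all genes and 3 adjusted over the list alone (Hspb7 at 0.93, camera adjusted p = 1.97e-04, and adjusted p = 0.396 with an estimated correlation). Notch pathway genes shifted downward here too, with 0 of 15 past the test over all genes and 6 lower adjusted over the list alone (Jag1 at -0.48, camera adjusted p = 1.97e-04, and adjusted p = 0.368 with an estimated correlation).

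Macrophage markers had 15 of 17 positive values in treated knockouts, with Cd163 at 0.92. Of the 17, 0 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 1.97e-04, and adjusted p = 0.608 with an estimated correlation). These markers lay at 0.917 above their mean in treated knockout array 3 and at -0.109 and -0.444 in arrays 1 and 2. All 10 markers of dendritic and antigen presenting cells had negative values, with 0 past the test over all genes and 1 adjusted over the list alone (Cd209a at -0.93, camera adjusted p = 5.72e-04, and adjusted p = 0.368 with an estimated correlation). Untreated knockout array 2 lay at 0.509 against -0.075 and 0.124 in its group, and the treated arrays at -0.193, -0.337 and -0.093. Of 21 ion channel and calcium handling genes 0 passed over all genes. The ATP-sensitive potassium channel subunit Kcnj8, at -0.46, was the 1 lower adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.478 with an estimated correlation).

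The limma count in knockouts was 5 at the adjusted threshold and 1535 at an unadjusted p under 0.05, and 13 lists passed camera (8 upward), 1 of them with an estimated correlation. It was 12 without WT untreated array 1, 1 without WT DOCA/salt array 3, and 1 and 3 without knockout untreated arrays 1 and 3. Without knockout DOCA/salt arrays 1, 2 and 3 it was 0, 3 and 2, and each of the 5 genes lost its call without knockout DOCA/salt array 1. Adm and Slc22a2 were called higher in both genotypes, 2 genes against 0.0205 expected for independent lists. Each gene's spread was pooled over the same 12 arrays in both contrasts, so the lists are not independent and this excess is no test. Of the 155 genes called in WT 121 (78.1%) had the same sign in knockouts, with a correlation over all genes, which are not independent replicates, of 0.216. Their median change was 0.699 in WT and 0.112 in knockouts along the WT direction, and 54 were small RNAs. Without small RNAs the medians were 0.579 and 0.152 for 71 higher genes and -0.424 and -0.141 for 30 lower genes. Choosing genes called in WT tends to raise the WT sizes.

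The interaction tested whether the response to DOCA/salt differed between genotypes, and 4 genes other than small RNAs passed. Ccl8 had a response of 1.77 in WT and -0.74 in knockouts (difference -2.51, SE 0.30, adjusted p = 0.0177). Cilp had responses of 1.86 and 0.17 (difference -1.69, SE 0.23, adjusted p = 0.0407). The elastic fibre protein Mfap5 had responses of 0.75 and -0.13 (difference -0.87, SE 0.12, adjusted p = 0.0468). The deubiquitinase Usp2, a clock-controlled gene, had responses of -0.70 and 1.05 (difference 1.76, SE 0.23, adjusted p = 0.0318), neither of which passed within its genotype (adjusted p = 0.0885 in WT and 0.104 in knockouts).

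By camera, 12 lists had a lower or higher response in knockouts (8 lower), and 0 held with an estimated correlation or by fry. Extracellular matrix genes had 25 of 29 negative differences, with 0 past the test over all genes. Lower adjusted over the list alone were 5, with Col15a1 at -0.73, Tnc at -0.82 and Postn, a matrix protein of remodelling tissue, at -1.40 (camera adjusted p = 2.13e-07, and adjusted p = 0.49 with an estimated correlation). Cell cycle genes had 26 of 27 negative differences and 0 past the test either over all genes or adjusted over the list alone (Kif11 at -0.21, camera adjusted p = 2.13e-07, and adjusted p = 0.54 with an estimated correlation). Their mean deviation was 0.106 in treated knockout array 3 against -0.101 and -0.087 in arrays 1 and 2. Synthetic smooth muscle genes had 0 of 17 past the test over all genes and 2 lower adjusted over the list alone (S100a4 at -1.30, camera adjusted p = 0.0016, and adjusted p = 0.468 with an estimated correlation). The 10 dendritic and antigen presenting markers all had negative differences, with 0 past the test over all genes and 1 adjusted over the list alone (Cd209a at -1.75, camera adjusted p = 2.51e-06, and adjusted p = 0.193 with an estimated correlation). Arrays of this list that lay apart from their groups were untreated knockout array 2 (0.509, against -0.075 and 0.124) and WT untreated array 3 (-0.397, against 0.03 and -0.152).

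Altogether 10 genes passed the limma interaction test and 1028 had an unadjusted p under 0.05. Of the 10, 7 had a positive and 3 a negative difference, and 6 of the positive ones were small RNAs. The count was 73, 1 and 5 without WT untreated arrays 1, 2 and 3, and 5, 2 and 1 without WT DOCA/salt arrays 1, 2 and 3. It was 3, 5 and 6 without knockout untreated arrays 1, 2 and 3, and 1 and 1 without knockout DOCA/salt arrays 1 and 2. With small RNAs left out, chosen after seeing the data, 0 genes passed. The differences of Ccl8, Cilp, Usp2 and Mfap5 were unchanged in that fit, where their adjusted p was 0.102 to 0.113, since only the pooled variance and the adjustment differed. Each of the 4 named genes lost its call without at least 1 array, at adjusted p up to 0.0805 for Ccl8, 0.118 for Usp2, 0.163 for Cilp and 0.184 for Mfap5, while the sizes of their differences were at least 2.32, 1.62, 1.56 and 0.78.

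**Figure D3:**
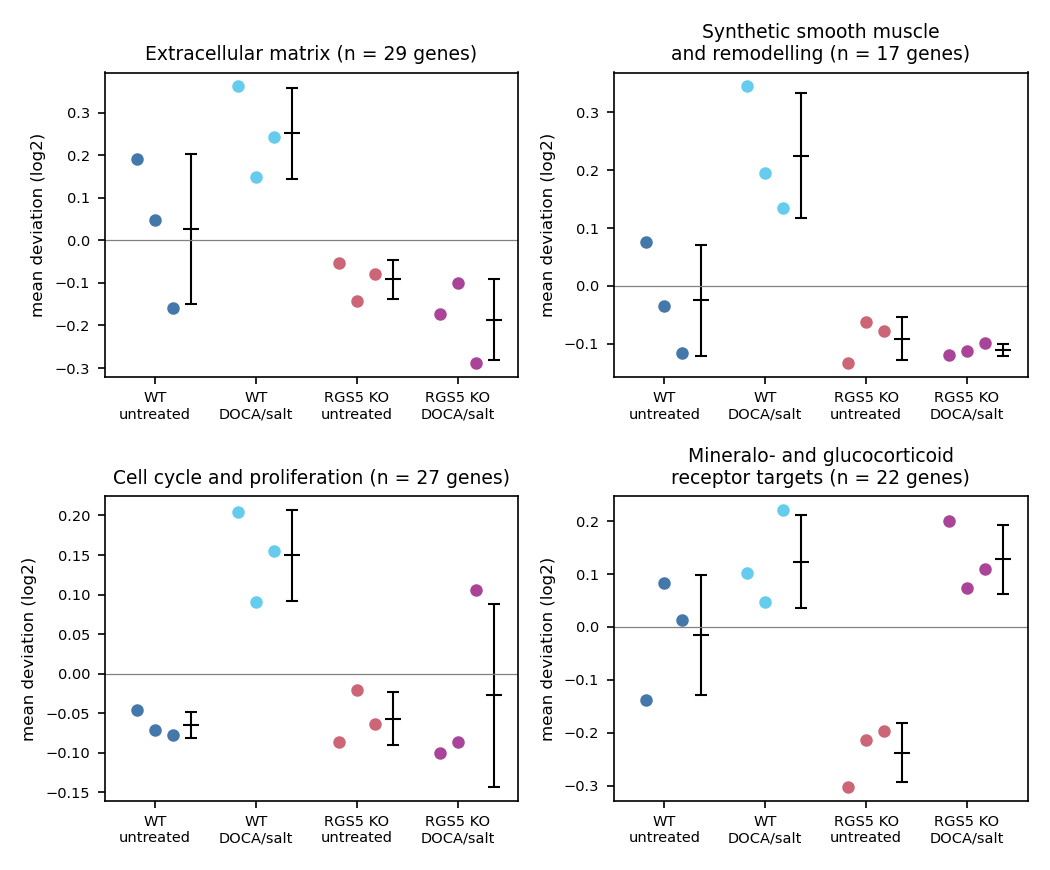
Mean deviation (log2, vertical axes) of the genes of 4 lists from their own mean over the 12 arrays, with points for arrays and bars for the mean ± SD of 3 arrays per group. Synthetic smooth muscle genes lie between 0.135 and 0.345 in treated WT arrays and between -0.12 and -0.099 in treated knockout arrays.

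In untreated animals the comparison of genotypes asked what the loss of RGS5 changed without DOCA/salt. Apart from Rgs5 the largest increase was in Nnt, the mitochondrial transhydrogenase whose C57BL/6J allele is disrupted, at 9.24 ± 0.09 (SD, n = 3) against 7.40 ± 0.29 (log2 fold change 1.84, SE 0.13, adjusted p = 1.32e-04). Edn1, the precursor of the vasoconstrictor endothelin 1, was higher as well (1.47, adjusted p = 0.0376). Its means were 9.81 in untreated knockouts and 8.34 in untreated WT, and which cells of the artery carried it was not tested. The growth factor Bmp4 (0.84, adjusted p = 0.008), the secreted kinase Pkdcc (0.82, adjusted p = 0.00401) and Wdfy1 (0.76, adjusted p = 0.023) were also higher, as were Bpgm (1.10), Ifi202b, which lies within 100 tested genes of Rgs5 (0.82), St3gal5 (0.81), Rnf152 (0.78) and Cpa6 (0.71). For Ifi202b and Cpa6 the WT readings were not above background, so the sizes are limited by it. Lower in knockouts were the glucocorticoid-induced chaperone Fkbp5 (-1.63, adjusted p = 0.0269), the plasma glutathione peroxidase Gpx3 (-1.51), the centromere chaperone Hjurp (-1.39), the cytokine Il33 (-1.35), Gda (-1.09) and the chemokine Cxcl14 (-1.03). Usp2 was at 6.64 ± 0.23 against 7.95 ± 0.28 in WT (-1.31, adjusted p = 0.00445), and metallothionein 2 (Mt2, -1.0) and spondin 1 (Spon1, -0.99) were lower too.

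Corticosteroid receptor targets shifted downward in untreated knockouts (camera adjusted p = 0.0193, and adjusted p = 0.566 with an estimated correlation), with members that went both ways. Mt2, Fkbp5 and Mt1 (-0.41) were lower and Edn1 was higher over all genes, and 18 of 22 did not pass. Of the list, 2 higher and 5 lower passed adjusted over the list alone. Of 22 unfolded protein response genes the chaperone Dnajb9 was lower by 0.65 (adjusted p = 0.0452) and 19 had negative values. It was also the 1 lower adjusted over the list alone (camera adjusted p = 0.00101, and adjusted p = 0.566 with an estimated correlation). Oxidative phosphorylation genes had 19 of 24 positive values, with Sdhc, which lies near Rgs5 on chromosome 1, higher over all genes (0.39, adjusted p = 0.023). Of the 24, 4 were higher adjusted over the list alone (camera adjusted p = 0.00224, and adjusted p = 0.566 with an estimated correlation). Inflammation and chemokine genes had Il33 and Cxcl14 lower over all genes and 3 of 20 lower adjusted over the list alone (camera adjusted p = 0.0193, and adjusted p = 0.654 with an estimated correlation). They lay at -0.096, 0.172 and 0.153 in WT and at -0.269, -0.067 and -0.283 in knockout arrays, so WT array 1 lay below knockout array 2. Extracellular matrix genes had 0 of 29 past the test over all genes or adjusted over the list alone, with 24 negative values (Timp1 at -0.58, camera adjusted p = 0.0331, and adjusted p = 0.75 with an estimated correlation). They lay at 0.192, 0.047 and -0.160 in WT and at -0.053, -0.142 and -0.080 in knockout arrays, so WT array 1 carried most of the shift and WT array 3 lay below every knockout array.

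Vascular tone genes had 1 of 26 past the test over all genes, the guanylate cyclase subunit Gucy1b1, a receptor for nitric oxide, which was higher (0.49, adjusted p = 0.00822). There were 2 higher adjusted over the list alone (camera adjusted p = 0.99). Adipocyte markers had 12 of 15 negative values and 0 past the test either way (camera adjusted p = 0.0331, and adjusted p = 0.75 with an estimated correlation). Their deviations were -0.569, 0.044 and -0.593 in the knockout arrays against -0.758, 0.680 and 0.539 in the WT arrays. Circadian clock genes lay at -0.346, 0.208 and 0.290 in the WT arrays and at -0.319, -0.176 and 0.017 in the knockout arrays. They had 0 of 18 past the test either way (camera adjusted p = 0.0331, and adjusted p = 0.642 with an estimated correlation). Macrophage markers had 15 of 17 negative values, 0 past the test over all genes and 1 lower adjusted over the list alone (Cd163 at -0.72, camera adjusted p = 0.0193, and adjusted p = 0.75 with an estimated correlation).

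Of 5 genes known to differ between the C57BL/6J and C57BL/6N substrains, Nnt and Wdfy1 were higher over all genes and adjusted over the list alone (camera adjusted p = 0.106, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.00221). This list lay between 0.183 and 0.285 log2 relative to its mean in the knockout arrays and between -0.35 and -0.156 in the WT arrays. In a mean of 5 genes, Nnt (1.84) and Wdfy1 (0.76) made nearly all of this separation. The labels give over 15 generations of backcross to C57BL/6 and describe the WT animals both as littermates and as C57BL/6J, so each genotype count includes any difference in background.

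The limma count for untreated animals was 183, with 62 higher and 121 lower in knockouts, of which 1 and 55 were small RNAs, and 16 lists passed camera (6 upward), 0 of them with an estimated correlation. It was 625, 79 and 80 without WT untreated arrays 1, 2 and 3, 117 without WT DOCA/salt array 2, and 74, 302 and 74 without knockout untreated arrays 1, 2 and 3. Of the 20 named genes 8 (Nnt, Bmp4, Pkdcc, Rgs5, Hjurp, Usp2, Mt2 and Spon1) passed whichever array was left out. With small RNAs left out, chosen after seeing the data, 70 genes passed.

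Under DOCA/salt the comparison of genotypes asked how treated knockout arteries differed from treated WT arteries, the same WT arrays as in the first comparison. Cilp was at 5.67 ± 0.17 (SD, n = 3) in knockouts and 8.0 ± 0.27 in WT (log2 fold change -2.32, SE 0.16, adjusted p = 1.91e-04) and Ccl8 was lower by a similar amount (-2.26, adjusted p = 0.00126). S100a4 (-1.96), Postn (-1.76), Wfdc17 (-1.75), Ptprz1 (-1.48), the intermediate filament protein nestin (Nes, -1.39, adjusted p = 8.54e-06), the inhibitory IgG receptor Fcgr2b, which lies near Rgs5 (-1.38), and the dendritic cell lectin Cd209a (-1.36) were lower as well, with adjusted p up to 0.0387. Higher in knockouts were Nnt (1.71, adjusted p = 2.23e-04), the cytokine receptor Il31ra (1.13), the histone gene H2bc21 (0.91) and Notch3 (0.90, adjusted p = 0.0219). Also higher were Ifi202b (0.88), Gstk1 (0.85), Klk10 (0.83), Tcim (0.83), the lipid kinase Pi4k2a (0.82) and Pkdcc (0.81).

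Extracellular matrix genes shifted downward by camera in treated knockouts (adjusted p = 8.54e-15, and adjusted p = 0.309 with an estimated correlation). Of 29 tested genes 24 did not pass over all genes. Postn, Tnc (-1.16), the collagen Col15a1 (-0.92), the lysyl oxidase Loxl1 (-0.67) and the protease inhibitor Timp1 (-0.97) were lower than in treated WT. These are differences between genotypes and not falls with treatment: from untreated to treated knockouts Timp1 went from 6.28 to 6.54, and in WT from 6.85 to 7.52. The size for Tnc is limited by background, at a knockout reading of 4.82. Adjusted over the list alone 14 were lower (fry adjusted p = 0.0315). Synthetic smooth muscle genes had S100a4, Tnc and galectin 3 (Lgals3, -0.68) lower, and 14 of 17 did not pass over all genes. Of the 17, 8 were lower adjusted over the list alone (camera adjusted p = 1.67e-04, adjusted p = 0.309 with an estimated correlation, fry adjusted p = 0.0229). Cell cycle genes had 0 of 27 past the test over all genes and 8 lower adjusted over the list alone, with Mcm6 at -0.61 (camera adjusted p = 2.12e-08, and adjusted p = 0.594 with an estimated correlation). In this list treated knockout array 3 lay at 0.106, above treated WT array 2 at 0.09, and knockout arrays 1 and 2 lay at -0.101 and -0.087. Of 19 matrix proteases and inhibitors the plasminogen activator Plau (-0.77) and Timp1 were lower in knockouts. Adjusted over the list alone 1 higher and 3 lower passed (camera adjusted p = 0.197). Adventitial fibroblast markers had Mfap5 (-0.70) and Pi16 (-0.65) lower of 15, and 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.67). They had a mean deviation of -0.209 in treated knockout array 3 against 0.003 and -0.018 in arrays 1 and 2.

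Cholesterol synthesis genes had 15 of 16 positive values, with Stard4 higher (0.54, adjusted p = 0.04) and also the 1 call adjusted over the list alone (camera adjusted p = 1.66e-04, and adjusted p = 0.754 with an estimated correlation). Oxidative phosphorylation genes had Sdhc higher (0.39, adjusted p = 0.0309) and 4 of 24 higher adjusted over the list alone (camera adjusted p = 5.95e-04, and adjusted p = 0.432 with an estimated correlation). Mast cell markers had Fcer1a lower (-0.67, adjusted p = 6.24e-04), a gene within 100 tested genes of Rgs5. It was also the 1 of 10 called adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.754 with an estimated correlation). The list lay at 0.186, 0.052 and -0.198 in treated knockout arrays 1 to 3 and at 0.186, 0.189 and 0.172 in treated WT, so array 1 was level with WT and array 3 carried most of the shift. All 10 dendritic and antigen presenting markers had negative values, with Cd209a lower over all genes and adjusted over the list alone (camera adjusted p = 0.00231, and adjusted p = 0.309 with an estimated correlation). In the G protein and RGS family list Rgs4, the neighbour of Rgs5, was lower by 0.87 (adjusted p = 0.0371), and Gnai3 by 0.20 (adjusted p = 0.0378). These 2 of 23 were also those called adjusted over the list alone (camera adjusted p = 0.67). Of 19 contractile genes Actg2 was lower by 0.49 (adjusted p = 0.0219), and 1 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.67). Gucy1b1 was again higher (0.43, adjusted p = 0.0226).

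The limma count under treatment was 124, with 43 higher and 81 lower, of which 0 and 2 were small RNAs, and 9 lists passed camera (4 upward), 0 of them with an estimated correlation, and 3 passed fry. It was 54, 43 and 46 without WT DOCA/salt arrays 1, 2 and 3, 78 without knockout untreated array 3 and 66 and 44 without knockout DOCA/salt arrays 1 and 2. Of the 20 named genes 10 (Nnt, Pi4k2a, Pkdcc, Rgs5, Cilp, Ccl8, S100a4, Wfdc17, Nes and Fcgr2b) passed whichever array was left out. Between untreated and treated animals 11 genes higher and 17 lower in knockouts were shared, against 0.154 and 0.567 expected for independent lists. Of the 183 genes called in untreated animals 163 (89.1%) had the same sign under treatment. Their median difference was 0.623 in untreated animals, where they were chosen, and 0.199 under treatment along the same direction. Of the 183 genes 56 were small RNAs, whose levels stood apart in the WT untreated arrays. Medians without small RNAs were not taken for this comparison, so the 2 medians do not show that genotype differences shrink under treatment.

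Averaged over genotypes, DOCA/salt raised Adm (1.30, adjusted p = 0.00426), Cilp (1.02, adjusted p = 0.00479), Tnfrsf12a (0.83), Ifi205 (0.81) and the small heat shock protein Hspb7 (0.81). The Cilp average describes neither genotype, with responses of 1.86 in WT and 0.17 in knockouts. The glycogen-targeting phosphatase subunit Ppp1r3c fell by 1.14 (adjusted p = 0.0254), and Itih4 (-0.69), Notch3 (-0.66), Omd (-0.63) and Atp1b2 (-0.59) were lower as well. Pericyte markers shifted downward, with Notch3 and both subunits of a vascular ATP-sensitive potassium channel, Kcnj8 (-0.38) and Abcc9 (-0.29), lower over all genes. Of the 8, 2 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0366, and adjusted p = 0.572 with an estimated correlation). Corticosteroid receptor targets had Zbtb16 (0.79) and Sult1a1 (0.65) higher and 4 of 22 higher adjusted over the list alone (camera adjusted p = 8.96e-06, adjusted p = 0.106 with an estimated correlation, fry adjusted p = 0.0188). Notch pathway genes had Notch3, its ligand Jag1 (-0.41) and the effector Hey2 (-0.33) lower, with 6 of 15 lower adjusted over the list alone (camera adjusted p = 2.46e-05, adjusted p = 0.327 with an estimated correlation, fry adjusted p = 0.0283). In the G protein list Rgs2, a regulator of Gq, fell by 0.51, the phospholipase Plcb1 by 0.29 and Gnao1 by 0.22. This average gave 182 genes, 97 higher and 85 lower, 30 of the latter small RNAs. It gave 60, 75 and 101 without WT DOCA/salt arrays 1, 2 and 3, 68 and 79 without knockout untreated arrays 1 and 3 and 73 and 86 without knockout DOCA/salt arrays 1 and 3. Of the 10 named genes Adm and Cilp passed whichever array was left out.

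Averaged over treatments, knockout arteries had higher Nnt (1.78, adjusted p = 7.68e-06), Edn1 (1.07), the matrix protein Tnr, which lies near Rgs5 (1.05), the hedgehog-binding protein Hhip (1.02) and Pi15 (0.97). Besides Rgs5 (-7.36, adjusted p = 4.57e-11), lower genes were Cilp (-1.48, adjusted p = 2.52e-04), the chemokine Ccl6 (-1.34), S100a4 (-1.31) and Hjurp (-1.15). Cilp means were 6.13 in WT and 5.5 in knockouts when untreated, and 8.0 and 5.67 under treatment, so its average describes neither state. Extracellular matrix genes had 6 of 29 lower over all genes, among them Postn (-1.05), Tnc (-0.75) and Col15a1 (-0.56). Of the 29, 11 were lower adjusted over the list alone (camera adjusted p = 9.02e-09, adjusted p = 0.704 with an estimated correlation, fry adjusted p = 0.0413). Of 39 tested neighbours of Rgs5 on distal chromosome 1, 2 were higher and 6 lower over all genes, with Fcgr2b at -1.07, Uap1 at -0.68, Rgs4 at -0.51 and Sdhc at 0.39. They had 5 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.382). This average gave 564 genes, 260 higher and 304 lower, of which 3 and 50 were small RNAs. It gave 954 and 327 without WT untreated arrays 1 and 2, 331, 297 and 299 without WT DOCA/salt arrays 1, 2 and 3. It was 324, 854 and 352 without knockout untreated arrays 1, 2 and 3 and 349 without knockout DOCA/salt array 2. Among the 10 named genes Hhip alone lost its call without some array.

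**Figure D4:**
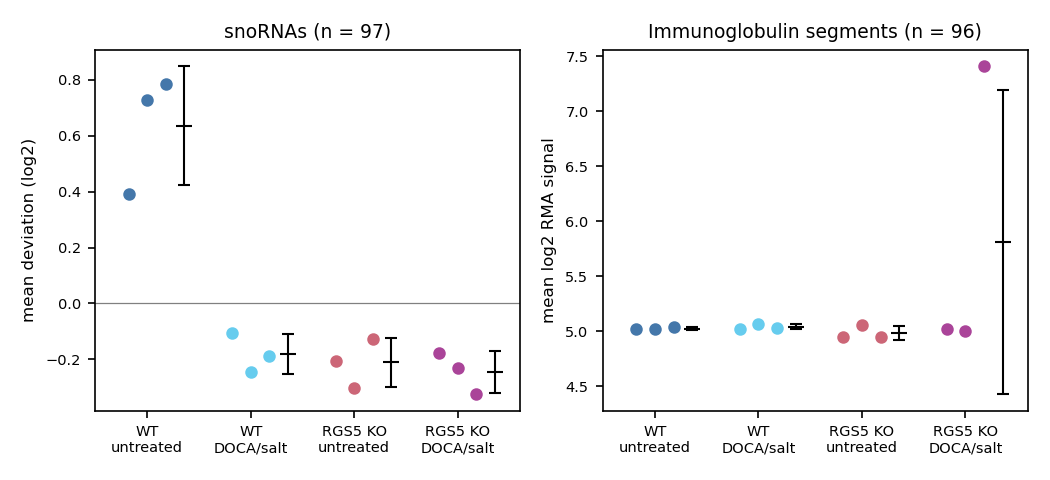
Mean deviation of 97 snoRNAs from their own mean over the 12 arrays (log2, left axis) and mean intensity of 96 immunoglobulin segments (log2, right axis) in the 4 groups, with points for arrays and bars for the mean ± SD of 3 arrays. The 3 WT untreated arrays lie between 0.392 and 0.787 for snoRNAs, and 1 treated knockout array lies at 7.41 for immunoglobulin segments.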

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

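Chosen only after the results were seen were the tests of a response of the treated knockout group, of short RNA recovery, of a DOCA/salt and genotype effect on short RNAs, of the Nnt alleles and of all the other splits of the arrays, together with the fits that left out small RNAs or both arrays that stood apart. The rule that voids a marker list with most genes near the floor or already expressed in the artery was also set after the values were seen.

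The response to DOCA/salt differed between genotypes for 10 genes by the interaction test, each difference being the knockout response minus the WT response in log2. The chemokine Ccl8 had a difference of -2.511 (adjusted p = 0.0177) and the matrix protein Cilp one of -1.691 (adjusted p = 0.0407), and the elastic fibre protein Mfap5 had one of -0.872 (adjusted p = 0.0468). The deubiquitinase Usp2 differed by 1.755 (adjusted p = 0.0318). Short RNAs made up the rest, with Snora44 at 1.732 (adjusted p = 0.00347), Snora5c at 1.983, Snord15b at 2.352, the ribosomal 5S gene n-R5s136 at 1.755 and Snord22 at 1.64 (each adjusted p = 0.0177), and Snord17 at 1.056 (adjusted p = 0.0407). Their WT responses lay between -2.424 and -1.166 and their knockout responses between -0.132 and 0.141.

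Among 100 splits of the arrays, 4 gave as many interaction genes as the real 10, the real split included, and the highest of the others gave 118. That split kept the WT labels and set knockout DOCA/salt array 1 and knockout untreated arrays 1 and 3 against the other 3 knockout arrays. A split that calls several times the real count points to a structure among the knockout arrays apart from treatment. The share is under 0.05, but 6 of the 10 genes are short RNAs that stand apart in the WT untreated arrays, and the other split above called many more genes. Chance is therefore not taken as excluded for a difference between the genotypes' responses. Without small RNAs Ccl8, Cilp, Usp2 and Mfap5 kept the same differences, at adjusted p from 0.102 to 0.113. For DOCA/salt in knockouts, 2 of the 10 splits of the 6 arrays gave as many genes as the real 5, and the highest other gave 33 from the same grouping of the knockout arrays. With 10 splits a share under 0.05 cannot be had, nor for DOCA/salt in WT (1 of 10, 155 genes, highest other 0), for genotype in untreated animals (1 of 10, 183 genes, highest other 6) or for genotype under treatment (1 of 10, 124 genes, highest other 1). For the averages 1 of 100 splits, the real one, gave 182 genes for treatment (highest other 17) and 1 of 100 gave 564 for genotype (highest other 36). These counts were known before the test was chosen, and 30 and 53 of these genes were small RNAs. Both averages use the WT untreated arrays, so the splits cannot tell treatment or genotype from another difference between the groups.

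In treated knockout array 3, 109 genes were over 1 log2 higher and 11 over 1 log2 lower than the mean of the other 2 arrays of its group, and 36 of the 42 genes over 3 log2 higher were immunoglobulin segments. In mean immunoglobulin signal, 2 of the other 2 arrays lay within the range of the 9 arrays of other groups. This restates that array 3 stood alone, and it argues only against a response shared by all treated knockouts. Lymph node tissue could be a source and stays open: 9 B cell and lymph node markers had a median of 0.003, but 7 of them lay under 5 log2 in all 3 arrays of the group, the bound set against it also asked for immunoglobulin genes to differ by over 3 log2 where their median difference was 1.162, and of the 5 lymph node stroma markers Cxcl13 alone made nearly all of the list's rise, at 11.99 against 6.20 and 5.47. Peritoneal macrophages had 14 markers at a median of -0.048, 4 of them under 5 log2 and 6 over 7.21 in the other 2 arrays. Mesothelial lining had 13 markers at a median of 0.008, 7 of them under 5 log2. The bounds set against both were met, but most of these markers lay near the floor or were already expressed in the artery. The rule set after the values were seen voids such lists, so both are left open. Plasma cells stay open too, with 12 markers at a median of 0.489, between the bounds set for and against them. Jchain lay at 10.33 against 4.47 log2, and Xbp1, which the artery also expresses, at 10.38 against 10.00. All 12 plasma cell markers had positive differences, from 0.25 for Sdc1 to 5.86 for Jchain. Their direction goes with plasma cells, though the bound set for them was not reached. Failure of the whole array fell between the bounds set for and against it. The median absolute difference of array 3 from its group was 0.0869 log2, against a highest of 0.0835 in other arrays. That highest value was from array 1 of the same group, whose comparison includes array 3. The large differences were mostly increases, and those over 3 log2 were mostly immunoglobulin segments, which argues against a failure that affects all genes alike. No other biological explanation was tested since no label sets this animal apart.

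In the 3 WT untreated arrays, 61 of the 64 small RNAs called lower in treated WT or in untreated knockouts lay higher than in all 9 other arrays, with a median difference of 1.282 log2 for the 56 snoRNAs among them. Because these RNAs were picked from contrasts against the WT untreated arrays, much of that separation and median was fixed by the choice. The hosts, other short RNAs and microRNAs below were not picked by their own values. All tested snoRNAs together, given above without such a choice, also lay higher in these 3 arrays. Levels of the host genes that carry these snoRNAs are argued against, since the median of 31 hosts was -0.013 log2. A difference in the recovery of short RNAs between RNA preparations could account for the pattern and stays open, with a median of 0.309 log2 for 14 other short RNAs between the bounds set for and against it, 4 of which (Scarna6, n-R5s136, Rmrp and Rny1) were themselves among the called small RNAs. An effect of both DOCA/salt and genotype cannot be told apart from it (61 of 64), because both contrasts use the same 3 WT untreated arrays and no other preparation of that group was measured. The 267 tested microRNAs had a median difference of 0.01 log2.

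Genotype differences were concentrated near Rgs5, where 27 of the 200 nearest tested genes (13.5%) passed in the average over treatments against 3.14% of 17080 others, a ratio of 4.302 (Fisher's exact test, two-sided, p = 3.88e-10). This is consistent with a segment of another strain's genome retained around the targeted gene, as the labels name embryonic stem cells of 129S6/SvEvTac and C57BL/6NTac origin, although effects of the missing gene on its neighbours were not tested. Probe mismatches with strain variants stay open, since 10 of the 27 were higher in knockouts, between the bounds set for and against mismatches. For Nnt, which is not near Rgs5, the lowest knockout array lay 1.471 log2 above the highest WT array, which may reflect a C57BL/6J allele in WT and a C57BL/6N allele in knockouts, and a difference in background elsewhere in the genome was not tested. Sdhc, Fcgr2b, Fcer1a, Rgs4, Uap1, Tnr and Ifi202b are among the 27, and their genotype differences carry this limit.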

How the results depend on the processing

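The fits without small RNAs, with the adipocyte covariate and without both arrays that stood apart were chosen after the results were seen. None of the 174 gene results followed by name reversed in the settings under which they were refitted, which were normalization, variance model, weights, block, arrays left out and the fits added later. For the other settings only counts were made. Counts are given in the order DOCA/salt in WT (155), DOCA/salt in knockouts (5), genotype untreated (183), genotype under treatment (124), interaction (10), average treatment (182) and average genotype (564), for those moved by over 1.5 times. Without a filter on dim genes the interaction gave 6 and the average treatment 121, and with a filter at the median the interaction gave 16. Trended and robust variance gave 8 in knockouts and 18 for the interaction. Fits to only the groups compared gave 11 in WT and 25 for genotype untreated, both of which use the WT untreated arrays. The same fits gave 6 in knockouts and 97 for genotype under treatment, which moved less. Fewer arrays to estimate the spread therefore do not alone account for the counts of 11 and 25. Most calls in those contrasts relied on a spread pooled with the other groups. Array weights gave 326 in WT, 285 for genotype under treatment, 16 for the interaction and 1079 for the average genotype. The replicate block gave 2 in knockouts, 117, 56, 2 and 76 for the contrasts after it up to the average treatment. A minimum of 1.5-fold kept 93 in WT, 97 and 60 for genotype, 46 and 114 for the averages. Tested against 1.2-fold, the counts were 22, 0, 41, 19, 6, 5 and 33. Leaving out small RNAs left every followed gene's own difference unchanged. Without them 55 passed in WT, 70 for genotype untreated and 0 for the interaction (1028 at an unadjusted p under 0.05 with them). The adipocyte covariate gave 234 in WT. Without both arrays that stood apart the counts were 250 in WT, 717 for genotype untreated, 73 for the interaction and 1196 for the average genotype. The cause of the other moves was not tested. Leaving out 1 array in turn gave ranges of 47 to 207, 0 to 12, 74 to 625, 43 to 173, 1 to 73, 60 to 224 and 297 to 954, and each highest count came without WT untreated array 1. The lowest came without WT DOCA/salt array 2 in WT, for genotype under treatment and for the average genotype, and without WT DOCA/salt array 1 for the average treatment. It came without knockout DOCA/salt array 1 in knockouts, without knockout untreated array 1 or 3 for genotype untreated, and without any of WT untreated array 2, WT DOCA/salt array 3 and knockout DOCA/salt arrays 1 and 2 for the interaction. For Rgs5 the range was -7.44 to -7.31. Lists past camera ranged over 9 to 16, 8 to 15, 8 to 17, 8 to 11, 8 to 18, 8 to 16 and 6 to 15 without 1 array. With an estimated correlation 0, 1, 0, 0, 0, 0 and 0 lists passed, and by fry 0, 1, 1, 3, 0, 3 and 5. Without both arrays that stood apart 19 lists passed in WT and 13 for the average genotype. Quantile normalization again and subtraction of array medians changed no call of 174 gene results followed by name. The deposited values were already quantile normalized, so both settings could change very little and are no real check. The mean of a gene's probe sets could change nothing with 1 probe set per gene. Of these 174 results, 6 lost and 4 gained a call under trended variance, 4 and 5 under weights, 55 lost it under the block, 32 without small RNAs, 16 with the adipocyte covariate, and 27 lost and 5 gained it without both arrays. Without at least 1 array 90 gene results followed by name lost their call. Genes near the dim limit of 4.57 log2 have little signal over background.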

Other observations

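All tests in this part used lists and contrasts fixed earlier, and only the comments on single arrays were chosen after the values were seen.

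Marker lists of several cell types gave no gene that passed. In each of the 7 contrasts 0 of 16 endothelial markers, 0 of 15 Schwann cell and nerve markers, 0 of 6 T and NK cell markers, 0 of 6 platelet markers and 0 of 9 keratinocyte markers passed, and none of these lists passed camera. Skeletal muscle markers had 15 of 16 negative values for genotype in untreated animals with 0 past the test either over all genes or adjusted over the list alone (Acta1 at -0.73, camera adjusted p = 0.0193, and adjusted p = 0.75 with an estimated correlation). In these markers WT untreated array 3 lay at 0.45 against -0.058 and -0.068 in arrays 1 and 2. Interferon response genes had 15 of 20 positive values in the same contrast and 0 past the test either way (Bst2 at 0.67, camera adjusted p = 0.0331, and adjusted p = 0.75 with an estimated correlation). In them knockout untreated array 2 lay at 0.614 and the others of its group at -0.147 and -0.087. Erythroid genes were too few to test as a list, and Bpgm, an enzyme of red cells, was the 1 of 4 that was higher in untreated knockouts.

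Vascular growth and pathway genes beyond those described above also gave calls. For genotype in untreated animals Bmp4 was the TGF-beta target that was higher over all genes, with 5 higher and 1 lower of 18 adjusted over the list alone (Bmp6 at 0.71, camera adjusted p = 0.0349, and adjusted p = 0.654 with an estimated correlation). Of 19 hypoxia genes Adm and the glucose transporter Slc2a1 (0.42, adjusted p = 0.0425) rose with DOCA/salt in WT and 4 higher and 2 lower passed adjusted over the list alone (camera adjusted p = 0.148). The fibrinolysis enzyme Plat rose in the same contrast (0.95, adjusted p = 0.00966), and Plau was at 0.62 (adjusted p = 0.0504). Averaged over genotypes, the small heat shock protein Hspb1 (0.43), the scavenger receptor Cd163 (0.66) and the sphingosine receptor S1pr1 (0.43) rose with DOCA/salt and the guanylate cyclase subunit Gucy1a1 fell by 0.37. Averaged over treatments, Il33 (-1.14), Cxcl14 (-0.86) and the LIM protein Fhl2 (-0.58) were lower and Scd2 (0.47) was higher in knockouts. For genotype under treatment the list of C57BL/6J against C57BL/6N markers had a median of -0.006 and a mean of 0.454. Its upward camera result (adjusted p = 0.0418, and adjusted p = 0.309 with an estimated correlation) differs in sign from the median. In this list Nnt was the 1 of 5 called over all genes, and 2 were called adjusted over the list alone. In the average over treatments Wdfy1 was higher as well (0.70, adjusted p = 0.00402).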
